A study of Mus musculus with 12 samples.

How the data were processed

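RNA of mouse 3T3 cells was hybridised on 12 arrays of 2 colours, 3 for each of 4 groups (control and Shld1 at 10 nM, 100 nM and 1 µM). Per the labels, each sample was labelled with Cy5 and a Stratagene mouse reference RNA with Cy3, without a dye swap, and arrays were read on an Axon scanner. The values used are the deposited log2 ratio per probe and array, with log base 2 assumed because the base is not stated. The authors' normalization, background correction and spot filters are not given in the sources used here. The scale (log base) and the centring stay unknown, and the direction, sample over reference, was taken from the dyes and from the signs of fibroblast and leukocyte genes rather than from a statement. Scanner intensities were not analysed here, so no intensity-dependent normalization and no filter on dim spots was applied, and signal over background is unknown. Between 13.3% and 21.0% of the 38784 probes were blank on an array, and array medians lay between -0.20 and -0.10. Pairs of arrays correlated at 0.690 to 0.875, and at most 0.146% of probes had equal values, to 0.001, in any pair.

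Probes were named from the platform's GEO annotation, with symbols updated by gene identifier from a RefSeq table of the mouse genome: 26173 probes had 1 symbol, 28 several and 12583 none. No positions in the genome are given. Each array was centred on its median. Probes with a value on at least 2 of the 3 arrays of every group were tested, 30357 in all, 21951 of them with 1 symbol (14524 genes); 8427 were left out, 2217 of which had no value on any array.

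Comparisons were fitted with limma 3.58.1 in R 4.3.3, with all 12 arrays and group as the only term, and p values were adjusted by Benjamini-Hochberg at 0.05. They were each dose against control, the mean of the 3 doses, a linear trend over dose rank, an F test over the doses and the differences between doses. Fold changes carry 95% intervals from the same fit. The test was checked on 10 simulated data sets. In each, 200 probes were changed, and it called 1.4% of changes of 1.5-fold, 26% of 2-fold, 89.6% of 4-fold and 99.2% of 8-fold. The noise was drawn independently for each probe. These rates hold for 200 changed probes, and with fewer the Benjamini-Hochberg threshold is stricter. Random sets of 20 probes moved by 0.5 had an unadjusted camera p under 0.05 in 10 of 10 and unmoved sets in 0 of 10. Genes that vary together were not simulated, so this says nothing on false calls of lists of such genes.

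The 25 gene lists were fixed before the data were examined, with 382 of 432 genes measured. They cover FK506-binding proteins, calcineurin and NFAT, the mTOR pathway, intracellular calcium release, the TGF-beta response, heat shock, the unfolded protein response, the proteasome, p53 targets, G1/S and G2/M genes, immediate early genes, the interferon response, NF-kB and cytokine genes, NRF2 and oxidative stress, xenobiotic metabolism, cholesterol synthesis, hypoxia and glycolysis, ribosomal proteins, fibroblast and matrix genes, and markers of adipocytes, macrophages, epithelium, endothelium and muscle. A gene's value was the mean of its probes measured on all 12 arrays or, with none, the probe with most values. Lists were tested by camera (preset correlation 0.01) on 12984 genes measured on every array, beside camera with an estimated correlation and fry, with Benjamini-Hochberg correction over the 25 lists. List averages per array were compared by exact permutation, and whole profiles by a permutation test of 100000 resamples.

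Genes named are, by a rule fixed before the data were examined, those that passed. Where fewer than 10 passed, they are the 10 higher and 10 lower genes with the smallest unadjusted p at 1 µM, 4 and 4 at the other doses and 3 for the mean, trend and F tests, among probes with 1 symbol measured on every array and passing over provisional symbols. From each list up to 4 members with the smallest p at 1 µM were eligible, and Fkbp1a, Fkbp4 and Fkbp5 were always reported. Il6 at 10 nM and the genes used for the direction of the ratio were added after their values were seen.

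Alternatives were values without centring, scaling to equal median absolute deviation, quantile normalization, stricter and looser probe filters, the replicate number of the labels as a block, fits of 2 groups alone, robust variance, array weights, 1 value per gene, other list tests and leaving out each array. A correction for position on the array, with probe numbers standing in for coordinates, and another for the ratio scale of each array were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.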

Results

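Gene expression was measured in mouse 3T3 cells, an established fibroblast line, left as controls or treated with Shld1 at 10 nM, 100 nM or 1 µM. Shld1 is a synthetic ligand that binds a destabilizing domain made from FKBP12 and shields proteins fused to it from degradation. Whether these cells carried such a fusion, and how long they were treated, is not given in the sources used here. Each of the 4 groups had 3 arrays, and each of the 12 arrays compared a sample in Cy5 with a mouse reference RNA in Cy3. Between 30649 and 33615 of 38784 probes had a value on an array, and 30357 probes were tested. All values are log2 ratios of sample over reference, with the log base taken as 2 and the direction taken from the dyes and from known fibroblast and leukocyte genes. If the deposited ratios ran the other way, every higher value below would be a lower one. The number of arrays limits the precision, and every p-value measures only the spread between these samples, since the labels do not say whether replicates were separate cultures.

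Several transcripts of matrix-producing fibroblasts stood well above the reference in control cells. The log2 ratio of Lum, which encodes the collagen-binding proteoglycan lumican, was 4.20 ± 0.27 (SD, n = 3), that of Postn (periostin) 3.18 ± 0.50 (n = 3) and that of Lox (lysyl oxidase) 2.14 ± 0.30 (n = 3), while the collagen gene Col3a1 was at 0.01 ± 0.24 (n = 3) and Fn1 (fibronectin) at 0.84 ± 0.13 (n = 3). Below the reference lay Ptprc, the leukocyte antigen CD45, at -2.62 ± 0.79 (n = 3) and the keratin gene Krt8 at -1.43 ± 0.40 (n = 3), although other epithelial genes lay above the reference, such as Epcam at 0.33 ± 0.35 (n = 3) and Cdh1 at 0.34 ± 0.49 (n = 3). These genes were chosen after their values were seen, and fibroblast and leukocyte genes served to set the direction of the ratio, so they are not independent evidence of it. Without a dye swap, a dye effect of a probe cannot be told apart from a difference between cells and reference.

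The main question, from the title of the series, is what Shld1 does to the transcripts of 3T3 cells, and the highest dose is the strongest test of it. At 1 µM, probe 27598, which has no gene name in the annotation, fell 13.0-fold against control. Its log2 ratio was 1.42 ± 0.50 (SD, n = 3) in controls and -2.27 ± 0.40 (n = 3) at 1 µM, a log2 change of -3.70 (SE 0.36, 95% interval -4.48 to -2.91; adjusted p = 0.00837, limma with Benjamini-Hochberg correction). All 3 arrays at 1 µM, between -2.64 and -1.84, lay below the lowest of the other 9, at 0.47. No other probe passed: of 30357 tested, 0 rose and 1 fell, and 1284 had an unadjusted p under 0.05 in limma where 1518 would by chance. Arrays with the same replicate number deviated together, which this fit does not model, so a count below 1518 cannot show that nothing changed. With that number as a random block the count was 1430. The call of probe 27598 held in 19 of 24 settings, with a range of adjusted p of 0.00160 to 0.0820 in limma. It ended in fits without control replicate 1 (adjusted p = 0.0735), control replicate 2 (0.0820) or 1 µM replicate 3 (0.0713). A fit of these 2 groups alone (0.0686) and the replicate number of the labels as a fixed block (0.0607) ended it too. Without 1 µM replicate 2, a probe of Plec passed as well, which made 2 calls.

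**Figure D1:**
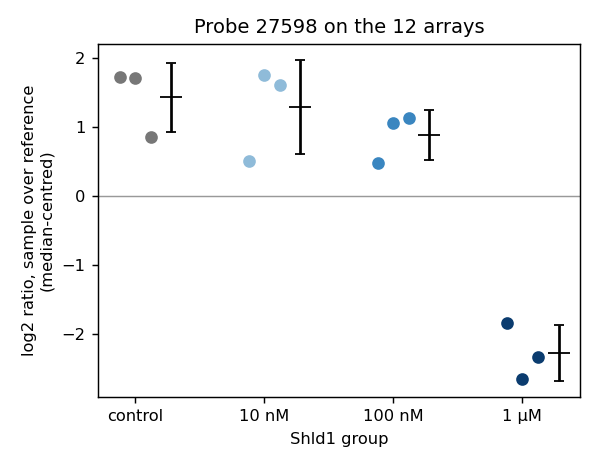
Log2 ratio of sample over reference for probe 27598 (vertical axis, median-centred) in the 4 groups (horizontal axis). Points are arrays and black bars are the mean and SD of 3; the 1 µM arrays lie between -2.64 and -1.84 and the other 9 at 0.47 or above.

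The gene lists fixed before the data were examined hold 382 measured genes, and none of these passed at 1 µM, over all 14524 genes or adjusted over the list alone (limma, Benjamini-Hochberg; 13 with an unadjusted p under 0.05). The FK506-binding proteins, the family from which the Shld1-binding domain was made, had a median log2 change of -0.06 over 14 measured members, 5 of them above 0. Fkbp1a, which encodes FKBP12 itself, was at 0.42 ± 0.13 (SD, n = 3) in controls and 0.44 ± 0.14 (n = 3) at 1 µM, a change of 0.02 (SE 0.14, 95% interval -0.28 to 0.32). The change of Fkbp4 was 0.04 (SE 0.19) and that of Fkbp5, a glucocorticoid-induced member, was -0.32 (SE 0.17). The pathways that drugs of the FK506 and rapamycin class act on had medians close to 0: 0.00 over 12 genes of calcineurin and NFAT, 0.03 over 16 of the mTOR pathway and 0.02 over 10 of intracellular calcium release. Within them the values were 0.36 (SE 0.26) for the calcineurin regulator Rcan1, 0.26 (SE 0.18) for Rictor and 0.50 (SE 0.19) for the calcium channel gene Itpr3. None of these 4 lists passed camera, with adjusted p from 0.542 to 0.692.

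The 16 measured genes of cholesterol synthesis were lower as a group at 1 µM, 15 of them below control, with a median log2 change of -0.36. Among them were Cyp51 at -0.50 (SE 0.24), Nsdhl at -0.45 (SE 0.18), Mvk (mevalonate kinase) at -0.36 (SE 0.18) and Sqle (squalene epoxidase) at -0.35 (SE 0.17), and none passed alone. The list passed camera with its preset correlation (adjusted p = 1.11e-05), but with an estimated correlation its adjusted p was 0.763 and by fry 0.802. Over 24 settings the range was 8.1e-07 to 0.802, and the 22 in which it passed all used the preset correlation. Averaged over the list, the log2 ratio was 0.82 ± 0.12 (SD, n = 3) in controls and 0.51 ± 0.09 (n = 3) at 1 µM, with an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 can give. The difference between doses was not tested for the list.

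Genes of fibroblasts and their matrix were also lower at 1 µM as a group, 16 of 19 below control with a median of -0.21. Lum went from 4.20 ± 0.27 (SD, n = 3) to 2.94 ± 0.47 (n = 3), a change of -1.26 (SE 0.47), and the values were -0.45 (SE 0.18) for the collagen gene Col3a1, -0.38 (SE 0.17) for Dcn (decorin) and -0.39 (SE 0.19) for the growth factor receptor gene Pdgfrb. The list passed camera with its preset correlation (adjusted p = 0.0108), not with an estimated correlation (adjusted p = 0.763) or by fry (adjusted p = 0.802), and list averages per array overlapped between the groups (exact permutation p = 0.2). That call was lost without control replicate 1 (median -0.10, adjusted p = 0.548) or 1 µM replicate 3 (median -0.06, adjusted p = 0.435) and with quantile normalization (median -0.19, adjusted p = 0.119), in a range of 0.00113 to 0.802 over 24 settings. Macrophage markers had a median of 0.21 over 11 genes, with Adgre1 at 1.04 (SE 0.44), and epithelial markers 0.14 over 9 (0.22 over the 8 that camera tested), with Epcam at 0.55 (SE 0.25). Neither passed camera (adjusted p = 0.542 and 0.202), except without control replicate 3, where both did (medians 0.52 and 0.38, adjusted p = 0.0345 and 0.00830; ranges 0.0345 to 0.965 and 0.00830 to 0.814). The macrophage median ran from -0.08 to 0.52 over the settings.

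**Figure D2:**
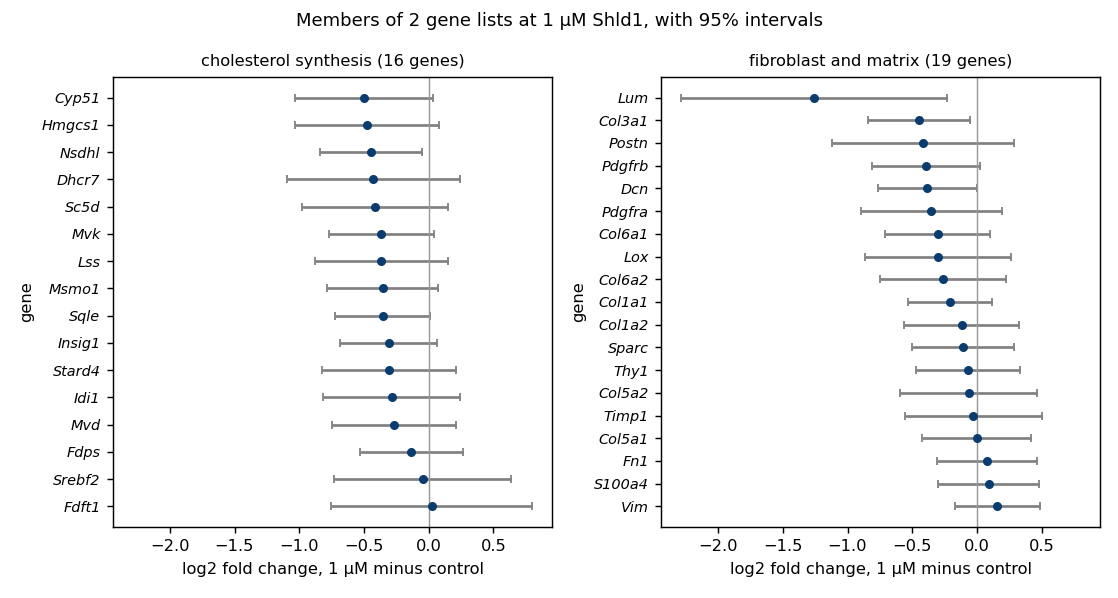
Log2 fold change at 1 µM against control (horizontal axis) of the 16 cholesterol synthesis genes and the 19 fibroblast and matrix genes, with points for gene values and bars for 95% intervals from limma. In all, 15 of 16 and 16 of 19 points lie below 0, and no gene passed the test alone.

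No stress or damage programme passed the list test at 1 µM. The medians were 0.04 over 13 heat shock genes, 0.05 over 18 genes of the unfolded protein response, -0.06 over 30 proteasome genes, 0.05 over 15 NRF2 and oxidative stress genes, 0.00 over 16 p53 targets and -0.01 over 12 genes of xenobiotic metabolism. Single values were -1.63 (SE 0.86) for Chac1 of the unfolded protein response, 1.17 (SE 0.59) for the thioredoxin gene Txn1, -0.78 (SE 0.27) for Pdia6, which encodes a disulfide isomerase of the endoplasmic reticulum, -0.66 (SE 0.24) for Dnajc3 and -0.81 (SE 0.27) for the death receptor gene Fas. The medians of growth and signalling lists were -0.09 over 17 G1/S genes, 0.02 over 17 G2/M genes, -0.03 over 25 ribosomal proteins, -0.07 over 18 genes of the TGF-beta response, 0.11 over 20 immediate early genes and 0.09 over 19 genes of hypoxia and glycolysis. The immediate early phosphatase gene Dusp1 was at 0.64 (SE 0.34) and Vegfa at 0.58 (SE 0.30). The interferon response had a median of 0.03 over 18 genes, with Mx2 at 0.97 (SE 0.35), and the NF-kB and cytokine genes 0.01 over 18, with Il6 at 0.58 (SE 0.24) and Ptgs2 at 0.45 (SE 0.20). Markers of other cell states gave 0.03 over 12 adipocyte, -0.01 over 6 endothelial and 0.07 over 8 muscle genes. None of these lists passed camera, the smallest adjusted p being 0.179, for hypoxia and glycolysis, which passed without control replicate 3 (median 0.22, adjusted p = 0.00830) and 1 µM replicate 1 (0.19, 0.0126) and with arrays scaled to equal spread (0.15, 0.0303), in a range of 0.00830 to 0.802. The interferon list passed without 1 µM replicate 1 (median 0.11, adjusted p = 0.0472, range 0.0472 to 0.965). Median and mean had opposite signs for the adipocyte, unfolded protein and xenobiotic lists (means -0.05, -0.11 and 0.09), and camera was positive against a negative median for the ribosomal, xenobiotic and endothelial lists (the endothelial test used the 3 genes measured on every array, with a median of 0.23) and against a negative mean for the adipocyte, unfolded protein, ribosomal and endothelial lists. At 100 nM, at 10 nM and for the mean of the doses, camera and the median had opposite signs for 8, 4 and 10 lists, and median and mean for 8, 3 and 8, none of which passed.

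**Figure D3:**
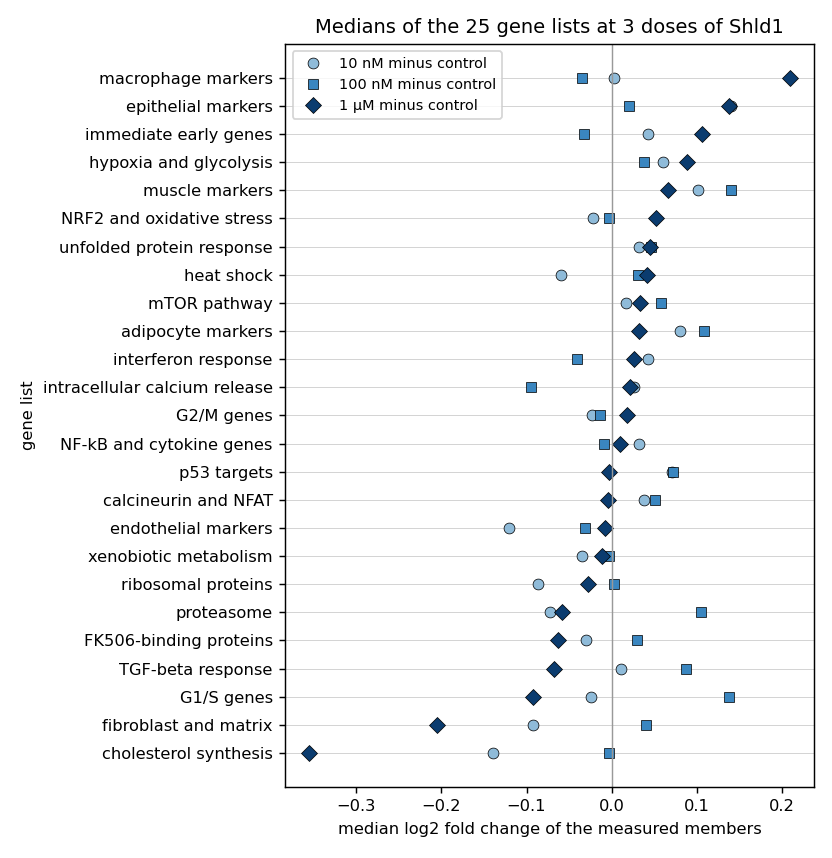
Median log2 fold change against control (horizontal axis) of the measured members of each of the 25 gene lists (vertical axis) at 3 doses of Shld1. The medians run from -0.36 for cholesterol synthesis to 0.21 for macrophage markers, both at 1 µM.

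Among the genes with the smallest unadjusted p at 1 µM, which did not pass, several large values stood on a probe while the gene's other probes lay closer to 0. Shkbp1 had a log2 value of -1.77 (SE 0.30, adjusted p = 0.390 in limma) against 0.14 on its other probe, and Scrn1 -1.66 (SE 0.34) against -0.08 to 0.27 on 3 others. The cytoskeletal linker gene Plec gave -1.37 (SE 0.25) and -0.17 to 0.20 on 12 others, and Epb41l2, a membrane skeleton gene, 1.18 (SE 0.21, adjusted p = 0.390) against -0.17 to 0.45 on 3 others. All other probes had the sign of the named probe for Dst, with 1.00 (SE 0.27) and 0.07 to 0.59 on 6 others, Pcmt1, with -0.93 (SE 0.23) and -0.61 and -0.16 on its others, Ppp6c (0.94, other 0.29), Gramd3 (-1.12, other -0.38) and Spn (1.10, other 0.08). The remaining higher values were those of Tbc1d9 (1.13), Cebpg (1.06), Lcn4 (0.90), the kinase gene Pim1 (0.85), Ppp2r5c (0.75, others -0.21 and 0.06) and Uhmk1 (0.52, others -0.23 and -0.02). The remaining lower values were those of Prr14l (-1.34), Camk1d (-1.11), Tmed6 (-1.07), Plcb4 (-0.92) and Kirrel2 (-0.87).

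For most tested probes the interval excluded a doubling of the measured ratio at 1 µM. This does not cover the 8427 probes left out. Signal over background is unknown, which limits what the interval of a dim probe says of its transcript. The 95% interval of the log2 change lay between -1 and 1 for 77.9% of the 30357 probes and for 330 of the 382 listed genes (86.4%). Estimates beyond 2-fold were made for 504 probes, 204 higher and 300 lower, and the median size of the log2 change was 0.16. On data simulated with independent noise and 200 changed probes in each set, the test called 26% of changes of 2-fold and 89.6% of those of 4-fold. Where fewer probes change, the Benjamini-Hochberg threshold is stricter, so these shares may be too high for the real comparison.

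At 100 nM no transcript passed the test. The genes with the smallest unadjusted p were the olfactory receptor gene Olfr73 at -1.67 (SE 0.25, n = 3, adjusted p = 0.713 in limma), Ldb2 at 1.42 (SE 0.28) with 0.00 on its other probe, Rsph1 at -1.38, Cd72 at -1.26 and Plcb4, a phospholipase C gene, at -0.998 (SE 0.18). Further genes by that rule were Nkd2 (0.84), Uhmk1 (0.59, with -0.35 and 0.04 on its others) and the talin gene Tln1 (0.57, with a median of 0.15 over its 60 other probes). Fkbp1a was at 0.06 (SE 0.14), Fkbp4 at 0.05 (SE 0.19) and Fkbp5 at -0.41 (SE 0.17). Cholesterol synthesis genes had a median of 0.00 with 9 of 16 below control, and fibroblast and matrix genes 0.04 (mean -0.03) with 7 of 19 below. In limma 0 of 30357 probes passed, with 980 at an unadjusted p under 0.05, and none of the 382 listed genes passed, over all genes or adjusted over the list alone (4 unadjusted). No list passed camera (3 of 25 unadjusted, smallest adjusted p = 0.286), but 4 did without control replicate 1: the proteasome (median 0.14), G1/S (0.21), interferon (-0.11) and macrophage lists (-0.20). Without 100 nM replicate 3 the cholesterol list did (median -0.19). The interval lay within a doubling either way for 80.4% of probes and 338 listed genes.

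At 10 nM the cytokine gene Il6 passed when its p was adjusted over the list alone. It was the only such call over the 25 lists at each of the 3 doses. That adjustment was made for each list and dose separately and does not allow for their number. Its log2 ratio was -0.06 ± 0.36 (SD, n = 3) in controls and 1.05 ± 0.39 (n = 3) at 10 nM, a change of 1.10 (SE 0.24; adjusted p = 0.0154 over the 18 NF-kB and cytokine genes alone, 1.00 over all genes, limma). It was 0.51 (SE 0.27) at 100 nM, where 2 arrays had a value, and 0.58 (SE 0.24) at 1 µM, and it was singled out after its values were seen. By smallest unadjusted p, the named genes were Art5 at -1.51 (SE 0.37), the sialophorin gene Spn at 1.21 (SE 0.29, -0.05 on its other probe), Shkbp1 at -1.15 (0.03 on its other), Lrp1 at -1.13 (a median of 0.09 over 93 others), an immunoglobulin kappa variable gene at 0.92, Nt5c1b at 0.74, Ccdc181 at 0.65 and Umodl1 at -0.65. Fkbp1a was at -0.05 (SE 0.14), Fkbp4 at -0.01 (SE 0.19) and Fkbp5 at -0.21 (SE 0.17). Cholesterol synthesis genes had a median of -0.14 with 10 of 16 below control, and fibroblast and matrix genes -0.09 with 15 of 19 below. Over all probes 0 passed in limma, with 812 at an unadjusted p under 0.05, and of the listed genes 0 passed over all genes (8 unadjusted). No list passed camera (4 of 25 unadjusted, smallest adjusted p = 0.285), though ribosomal proteins did without control replicate 2 (median -0.18), hypoxia and glycolysis without 10 nM replicate 1 (0.19), and hypoxia and glycolysis (0.20) with fibroblast and matrix genes (-0.18) without control replicate 3. The interval lay within a doubling for 80.0% of probes and 334 listed genes.

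No transcript passed for the mean of the 3 doses. The smallest p values belonged to Plcb4 at -0.80 (SE 0.15), Shkbp1 at -1.18 (SE 0.24) and Ldb2 at 1.07 (SE 0.23), and 0 of 30357 probes passed in limma, with 959 unadjusted. The cholesterol synthesis list, 13 of 16 genes below control with a median of -0.14, passed camera for this mean (adjusted p = 0.0374), not with an estimated correlation (adjusted p = 1.00) or by fry (0.988). That call ended in 8 of the 12 fits without an array, namely control replicates 1 (0.418) and 3 (0.0627), 10 nM replicates 1 (0.166) and 2 (0.0518), 100 nM replicates 1 (0.176) and 2 (0.153), and 1 µM replicates 1 (0.122) and 2 (0.0667), in a range of 0.000179 to 1.00. The median was -0.09 without control replicate 1 and -0.17 without control replicate 3. Without control replicate 3 it was replaced by 3 other lists: hypoxia and glycolysis (median 0.17), fibroblast and matrix (-0.18) and epithelial markers (0.30), and without 100 nM replicate 3 it was joined by fibroblast and matrix (-0.11).

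A linear trend over control and the 3 doses passed in probe 27598, at -1.15 per step (SE 0.11, adjusted p = 0.0101, limma). This trend follows the drop at 1 µM: the log2 change was -0.14 at 10 nM and -0.54 at 100 nM (95% interval -1.33 to 0.24), where it did not pass. It held in 19 of 23 settings and was lost, among others, without control replicates 1 (0.0776) or 2 (0.0865) or 1 µM replicate 3 (0.0761), in a range of 0.00153 to 0.0865, and without 1 µM replicate 2 it was joined by Plec and Scrn1. Among probes with 1 gene symbol measured on every array, the smallest p for the trend were those of Epb41l2 at 0.44 per step (SE 0.07, adjusted p = 0.347), Plcb4 at -0.33 and Plec at -0.43. In the test of any difference among the groups probe 27598 passed (adjusted p = 0.0199, limma; 1005 unadjusted), and among those named probes Epb41l2 had the smallest p (adjusted p = 0.458), before Cd72 and Olfr73. That count was 0 without control replicates 1 or 2, 10 nM replicate 3, 100 nM replicate 2 or any 1 of the 1 µM arrays.

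Between doses, the same probe was lower at 1 µM than at 10 nM, where it stood at 1.29 ± 0.68 (SD, n = 3), by a log2 change of -3.56 (SE 0.36, 11.8-fold, adjusted p = 0.0126, limma). Against 100 nM, where it stood at 0.88 ± 0.36 (n = 3), the change was -3.16 (SE 0.36, 8.91-fold, adjusted p = 0.0451). No other probe passed either comparison, with 846 and 1463 unadjusted, and 0 passed between 100 nM and 10 nM (1158 unadjusted). The call against 10 nM held in 19 of 24 settings and was lost, among others, without 10 nM replicates 2 (0.0560) or 3 (0.135) or 1 µM replicate 3 (0.0953) and in a fit of the 2 groups alone (0.241), in a range of 0.00259 to 0.241. It was joined by Epb41l2 without 100 nM replicate 2 or 3 and by Plec without 1 µM replicate 2. The call against 100 nM passed in 9 of 24 settings (range 0.00835 to 0.358) and, among the fits without an array, only without control replicate 3 (0.0280) or 10 nM replicate 1 (0.00835).

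Arrays of the same dose group were not more alike in whole profile than arrays of different groups. Over the 25745 probes measured on every array, the mean correlation was 0.801 between arrays of the same group and 0.808 between arrays of different groups (permutation p = 0.839, n = 12 arrays). Arrays of a group never shared a replicate number, while some pairs of different groups did. Profiles grouped by that number (exact permutation p = 0.0145). This can lower the correlation within groups relative to that between them, so the permutation p cannot exclude grouping by dose. Across probes, which are not independent replicates, log2 changes correlated at r = 0.41 between 1 µM and 100 nM, 0.59 between 1 µM and 10 nM and 0.40 between 100 nM and 10 nM. Unchanged groups simulated against shared controls gave 0.50 for each pair. Without control replicate 3 the values were 0.61, 0.74 and 0.60, which were not set beside a simulation with 2 controls.

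**Figure D4:**
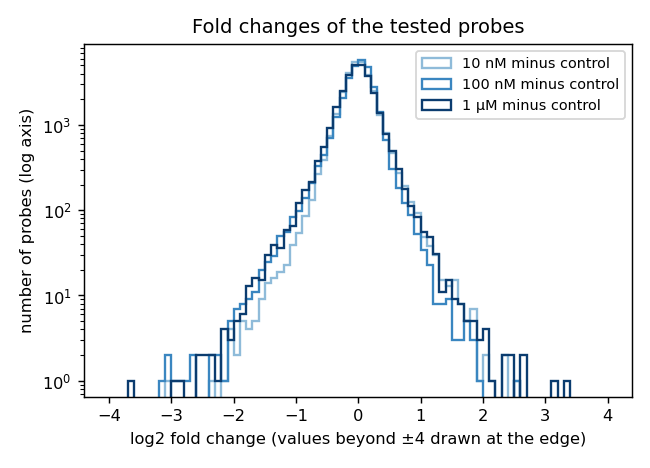
Number of probes (vertical log axis) by log2 fold change against control (horizontal axis) at 3 doses of Shld1, as outlines in steps of 0.1. The median size of the change is 0.16 at 1 µM and 0.15 at the lower doses, and the lowest value at 1 µM, -3.70, is that of probe 27598.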

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

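The tests of probe 27598, and those of the cholesterol synthesis genes other than the reassignment of arrays to groups, were chosen after the result was seen.

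Probe 27598 stood out because its log2 change at 1 µM differed from the other doses in a test of the difference itself, by -3.56 against 10 nM and -3.16 against 100 nM. A defect that spans neighbouring probe numbers is argued against by the 40 measured probes with numbers within 28 of it. Their median log2 change at 1 µM was -0.0212 (SD 0.36). Probe numbers stand in for positions on the array here, and a defect of the probe's own spot was not tested. A deviating array is argued against as well, since without any 1 of the 3 control and 3 treated arrays the change stayed at -3.51 or below, and an even fall over the dose steps by the interval at 100 nM, which ended at -1.33 where 2/3 of the change at 1 µM would be -2.46. An effect of 1 µM Shld1 on the transcript stays open as a hypothesis, found and tested on the same data, and the exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 can give, says nothing for or against it. The probe has no gene name, and the authors' unstated normalization and spot filters could not be tested.

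The cholesterol synthesis genes had a median log2 change of -0.36 at 1 µM, with 15 of 16 below control. The median stayed at -0.32 after the slope correction and at -0.34 after the position correction. This argues against an unequal ratio scale of the arrays and uneven hybridisation along the probe numbers as whole causes. The camera adjusted p was 0.000175 after the slope correction, with a range over settings of 8.1e-07 to 0.802. Without these corrections the call was lost in camera with an estimated correlation (adjusted p = 0.763) and by fry (0.802). Chance assignment of the arrays stays open as an explanation. Of 100 drawn splits of the 12 arrays, 7, the real one included, gave the list as small a camera p, down to 1.7e-10. These draws ignored the replicate number, with which arrays deviated together. Each real group holds 1 array of every number, so the draws cannot decide the question. Among the 10 splits of the 6 arrays compared, too few for a share under 0.05, the real p of 4.4e-07 was the smallest (next 0.00049). Controls that happen to stand high stay open too: the median at 100 nM against the same controls was 0.00 (-0.00367), but 1 of those arrays set it, the median being -0.19 without 100 nM replicate 3. An effect of 1 µM Shld1 on these genes remains a hypothesis, and the exact permutation p of 0.1, the smallest that 3 arrays against 3 can give, says nothing for or against it.

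Regrouping the arrays showed how often splits gave as many calls, with the real split included in each count. The splits ignored the replicate number, with which arrays deviated together, and none was made within replicate numbers. Their shares are therefore a description. For pairs of groups there are only 10 splits of 6 arrays, too few for a share under 0.05. As many probes as the real 1 at 1 µM against control were called in 2 of the 10 splits (highest other 1), as the real 1 at 1 µM against 10 nM in 3 (highest other 2) and as the real 1 at 1 µM against 100 nM in 1 (highest other 0). The real counts of 0 at 100 nM, at 10 nM and between them are matched by any split, so the splits cannot test them (highest other 1 in each). Over 100 drawn splits of the 12 arrays chance could not be excluded: as many probes were called in 22 for any difference among groups (real 1, highest other 4) and in 18 for the trend (real 1, highest other 2). For the mean of the doses the real count was 0, which any split matches (highest other 3).

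As many gene lists as the real 2 at 1 µM passed in 5 of the 10 splits, the real one included (highest other 7), with the same limit of 10 splits. The real counts of 0 at 100 nM and at 10 nM are matched by any split, so the splits cannot test them (highest other 9 and 6). For the mean of the doses, 57 of 100 splits, the real one included, passed as many as the real 1 (highest other 11). These draws, which ignored the replicate number too, could not exclude chance. Splits that pass 7, 9 or 11 lists, several times the real counts, point to a structure of the samples or to genes of a list that vary together beyond the preset correlation, and which of these accounts for them was not tested on the splits.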

How the results depend on the processing

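The position correction, the slope correction and the exact enumeration of array groupings were chosen after the data were seen. Counts of passing probes at 100 nM, at 10 nM, for the mean of the doses and between 100 nM and 10 nM were 0 in every setting that gave a value. For the counts below the cause was not tested, except where fewer arrays or the missing gene name of probe 27598 account for it. At 1 µM the count of 1 became 0 with the replicate number as a fixed block, in a fit of the 2 groups alone and with 1 value per gene. It ran from 0 to 2 when arrays were left out. The trend count of 1 became 0 with the fixed block and 1 value per gene (0 to 3 without an array). Against 10 nM the count of 1 became 2, with Epb41l2 higher, under quantile normalization, under the filter for probes measured on all 12 arrays and with a random block. It became 0 with the fixed block, 2 groups alone and 1 value per gene (0 to 2 without an array). Against 100 nM it became 0 with at least 1 value per group, the fixed block, 2 groups alone, array weights, 1 value per gene and the slope correction (0 to 1 without an array). The F test count became 0 with the fixed block, array weights and 1 value per gene (0 to 1 without an array). Of the gene lists, the 2 that passed at 1 µM became 0 with an estimated correlation and by fry and 1 under quantile normalization (1 to 5 without an array). The 1 that passed for the mean became 0 with an estimated correlation, fry, cameraPR, quantile normalization, both blocks and the slope correction, and 3 with scaling to equal spread (0 to 3). At 100 nM and 10 nM 0 lists passed in the other settings, and 0 to 4 and 0 to 2 without an array. The share of probes with an interval inside a doubling at 1 µM stayed between 70.8% and 84.7%, within-group minus between-group correlation of whole profiles by dose between -0.0153 and 0.00138, and the correlation of changes between 0.49 and 0.74 for 1 µM and 10 nM, 0.29 and 0.61 for 1 µM and 100 nM, and 0.31 and 0.60 for 100 nM and 10 nM. Over 3488 alternative values of the 144 named gene results, 2 passed, both of Plec without 1 µM replicate 2, and 18 had the opposite sign with none passing. A fit of 2 groups alone gives no mean, trend or F test.

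Arrays with the same replicate number deviated together (r higher by 0.15 than for different numbers, exact permutation p = 0.00926 over 216 renumberings), and the exact p was 0.037 after the slope correction and 0.00463 after the position correction, so neither removed it. Of the 18 pairs with the same number, 9 had r over 0.1, and the number is not stated to be a batch. The mean r was 0.173 for number 1 and 0.132 for number 3, but 0.003 for number 2. With it as a fixed block, probe 27598 had an adjusted p of 0.0607 at 1 µM (limma; range 0.00160 to 0.0820). Whole profiles grouped by that number (exact permutation p = 0.0145). For dose the exact permutation p was 0.836, which cannot exclude grouping by dose, since arrays of a group never share a number. Signal over background is unknown here and limits every value of a dim probe.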

Other observations

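The levels and relations here were chosen after the values were seen, except for the gene lists, which were fixed before the data were examined.

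Against the reference RNA, control 3T3 cells had low ratios for the hypoxia and glycolysis list. It joins genes of glycolysis, the pathway that turns glucose into lactate, with hypoxia genes such as Vegfa. The list's median log2 ratio was -1.26, all 19 measured genes lay below 0 on all 3 controls, and 7 lay below by more than 2-fold, among them Vegfa at -2.12 ± 0.06 (SD, n = 3) and the glucose transporter gene Slc2a1 at -1.61 ± 0.23 (n = 3). Cholesterol synthesis stood high, with a median of 0.95 and 7 of 16 genes more than 2-fold above the reference on all 3 controls. The fibroblast and matrix list had a median of 1.11 with 8 of 19 genes above 2-fold, and 23 of 30 proteasome genes lay above 0 with a median of 0.53. Immediate early genes had a median of -0.41, 13 of 20 below 0 on all controls, and macrophage markers -0.68, with 7 of 11 below 0 on all controls. On all 12 arrays 569 probes (2.21% of 25745) were more than 2-fold above the reference and 356 (1.38%) more than 2-fold below. Samples were always in Cy5 and the reference in Cy3, so a dye effect of a probe is not separated from these differences. The zero of the ratio is the median of each array.

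Probes blank on all 3 arrays of a group and measured on all 3 of the other were counted. The spot filters are not given, so a blank need not mean an absent transcript. At 1 µM 71 were measured in controls alone and 24 in treated cells alone, 95 together, and 6 of the 9 other splits of these 6 arrays gave as many (66 to 331). The counts were 30 and 22 at 100 nM and 35 and 20 at 10 nM.

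The ratio scale of an array, its slope on the mean profile, was lower at higher array numbers, which run in the order of the replicate numbers, so the 12 arrays are not exchangeable and the permutation p is a description (n = 12, Pearson r = -0.759, permutation p = 0.00494, Spearman rho = -0.706, permutation p = 0.0133, and r = -0.639 without the 2 farthest arrays). The mean slope was 1.09 over the 4 arrays of replicate number 1, 1.01 over those of number 2 and 0.904 over those of number 3, and sets of 4 are too few for a correlation within them. By group the means were 0.997 in controls, 0.963 at 10 nM, 1.06 at 100 nM and 0.976 at 1 µM (n = 3 each). Deviations of probes with neighbouring numbers correlated at 0.0912 to 0.229 per array, against at most 0.0105 in shuffled order.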
